A study of Homo sapiens with 4 samples.

How the data were processed

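Single-end mRNA sequencing of the NTERA2 line was analysed from the read counts per gene that the authors deposited, 1 table per library. Per the labels' protocols, cells were grown in high-glucose DMEM with serum, total RNA was extracted with a column kit, libraries were made with a stranded mRNA kit, and the 4 libraries were pooled and sequenced on a NovaSeq instrument. The labels describe the line as a lung carcinoma derived from embryonic stem cells. NTERA2 is an embryonal carcinoma line, and the name of the line was used here.

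The values are counts, whole numbers that were not normalized, per the file headers. Reads were aligned with STAR 2.7.6a to hg19 (GRCh37), and FastQC was run, per the submitters' processing notes. Reads over exons were counted per gene with featureCounts of Subread 2.0.0 with strand setting 2, which counts reads on the reverse strand, and 4 threads, per the file headers. The command in the headers carries no option to count reads that map to several places or overlap several genes, so with the tool's defaults such reads were left out. Genes with near-identical copies and genes that overlap on the same strand are therefore uncertain. The annotation was listed by gene symbol, with 26364 genes. The gene listed as T is called TBXT here. Coordinates are 1-based on hg19 as the files give them.

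Samples were grouped by the labels into LacZ (replicates 1 and 3) and sh60 (replicates 1 and 2), and replicate numbers were taken from the library titles. The hairpin's sequence, the time of harvest and the way the hairpin was delivered were not given in the sources used here. Library totals were 42538561, 30338285, 33798665 and 44788461 counts for LacZ replicate 1, LacZ replicate 3, sh60 replicate 1 and sh60 replicate 2. At these depths the libraries had between 15509 and 16133 genes with 10 counts or more. Counts of replicate pairs differed by more than sampling noise (chi-square per degree of freedom 5.89 for the LacZ pair and 15.8 for the sh60 pair over genes with 20 counts or more), so no library was taken for a repeat of another. Confidence intervals are at 95%.

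The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3; glmQLFit and glmQLFTest) with TMM scaling, the group as the only term and all 4 libraries in the fit. Genes with low counts were removed with filterByExpr, which left 16040 genes of 20937 with at least 1 count. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The common biological coefficient of variation was 7.33%, with 2 residual and 15.9 prior degrees of freedom. CPM values use TMM-scaled library sizes and SEs are those of the log2 fold change. The script was tested on simulated data before use.

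Lists of genes were written before the data were examined, from general knowledge of embryonal carcinoma cells, lineages, stress responses and complexes linked with BEND3. They comprised 32 lists of named genes and 11 families taken from symbols, and included markers of fibroblasts and blood cells. Each was tested with camera (limma 3.58.1) at the preset correlation of 0.01, two-sided, with camera at an estimated correlation and with fry, adjusted over the lists. A list of mitochondrially encoded genes had 0 members in the files, and a list of X-linked cancer-testis genes had 1 tested member, so these were not tested as sets.

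Named genes followed a rule set at the same time. BEND3, CDKN1A, POU5F1, SOX2 and NANOG were always named. The 10 largest rises and 10 largest falls were taken among genes past the threshold whose sh60 libraries both lay beyond both LacZ libraries and whose higher group mean was at least 5 CPM. For each list up to 4 members past the threshold with the smallest p, or up to 2 where none passed, could be named. Some genes that the rule takes are not reported here. Other members named beside a count of 5 or fewer were chosen after their values were seen.

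Alternatives were DESeq2 size factors, upper-quartile scaling and library totals in edgeR, DESeq2 1.42.0, limma-voom, edgeR's robust option, no count filter, a stricter filter of 1 CPM in 2 libraries, edgeR's glmTreat against a fold of 1.2, and leaving out each library in turn. A correction for GC content and gene length was added after seeing the data. It removed loess trends of each library's log CPM on the GC content of the longest transcript in GENCODE, matched by symbol for 94.2% of tested genes, and on exon length as the files give it. That reference is on another genome build, so only its sequences were used. Called genes were counted per chromosome with Fisher's exact test.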

Results

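Messenger RNA was sequenced in NTERA2 cells, a human embryonal carcinoma line that expresses the genes of the pluripotent state and can differentiate along several lineages. The labels give 2 groups of 2 libraries. They name the groups BEND3 LacZ (replicates 1 and 3) and BEND3 sh60 (replicates 1 and 2). BEND3 is a BEN-domain protein that binds chromatin and represses transcription. LacZ is read here as the control and sh60 as a short hairpin RNA against BEND3, although the labels do not spell this out. The libraries held 42538561 and 30338285 counts in LacZ replicates 1 and 3, and 33798665 and 44788461 counts in sh60 replicates 1 and 2. Levels are given as CPM, a gene's counts scaled to the size of its library, and a single count was worth 0.0223 to 0.0330 CPM. The labels do not say whether replicates came from separate cultures, so every p-value below measures only the spread between these samples, which may be technical.

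The sh60 libraries held less BEND3 mRNA than the LacZ libraries, more mRNA of CDKN1A and of 31 of 39 other tested p53 targets, and less mRNA of 14 of 29 tested primitive streak and mesoderm genes, of which 5 rose and 10 did not pass. As sets these lists passed camera with its preset correlation and did not pass with an estimated correlation (adjusted p = 0.571 for each). Many lists share that adjusted value, a tie produced by the adjustment. Before adjustment the camera p with an estimated correlation was 0.0777 for the p53 targets and 0.144 for the mesoderm list. The correlation was estimated with 2 residual degrees of freedom. The question of the series, as its title gives it, is whether BEND3 holds differentiation genes down in pluripotent cells. BEND3 (chromosome 6, 107386385 to 107435636, hg19) measured 68.8 and 79.3 CPM in LacZ replicates 1 and 3 and 55.7 and 52.0 CPM in sh60 replicates 1 and 2. The group means were 74.1 ± 7.43 CPM (SD, n = 2) and 53.8 ± 2.63 CPM (SD, n = 2). By edgeR's quasi-likelihood test the log2 fold change was -0.46 (SE 0.098, adjusted p = 0.00168), and the lower level was seen in both sh60 libraries. The remaining level was 0.727 of that in LacZ (95% confidence interval 0.630 to 0.839). Without LacZ replicate 3 the log2 fold change was -0.36 and no longer passed (adjusted p = 0.153). Over all alternatives the adjusted p of BEND3 ran from 3.85e-05 to 0.153.

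Across the transcriptome, 4624 of 16040 tested genes (28.8%) differed between sh60 and LacZ at an adjusted p of 0.05 by the edgeR test, 2540 of them higher and 2084 lower in sh60. This balance depended on the scaling and turned with upper-quartile scaling (2424 higher and 2575 lower) and once GC and length trends were removed (2916 and 3695). Of the 4624 genes, 935 changed by a log2 fold change of 1 or more in size, 574 upwards and 361 downwards. Many of the changes were therefore small. The first principal component of log CPM separated the groups and held 76.0% of the variance, with LacZ replicate 1 at -25.4, LacZ replicate 3 at -38.9 and the sh60 libraries at 32.7 and 31.7. Without LacZ replicate 3 the number of changed genes was 2287, and without LacZ replicate 1 it was 2968. In simulated data for this comparison with 16040 genes, the same test recovered 70 of 100 genes changed by 1.5-fold and 95 of 100 changed 2-fold. It called 10 unchanged genes. The simulation changed a far smaller share of genes than the 28.8% called here, all of them at 1 CPM or more. Its libraries were drawn independently, without a difference shared by many genes between replicates. These rates may therefore not hold for the real data.

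**Figure D1:**
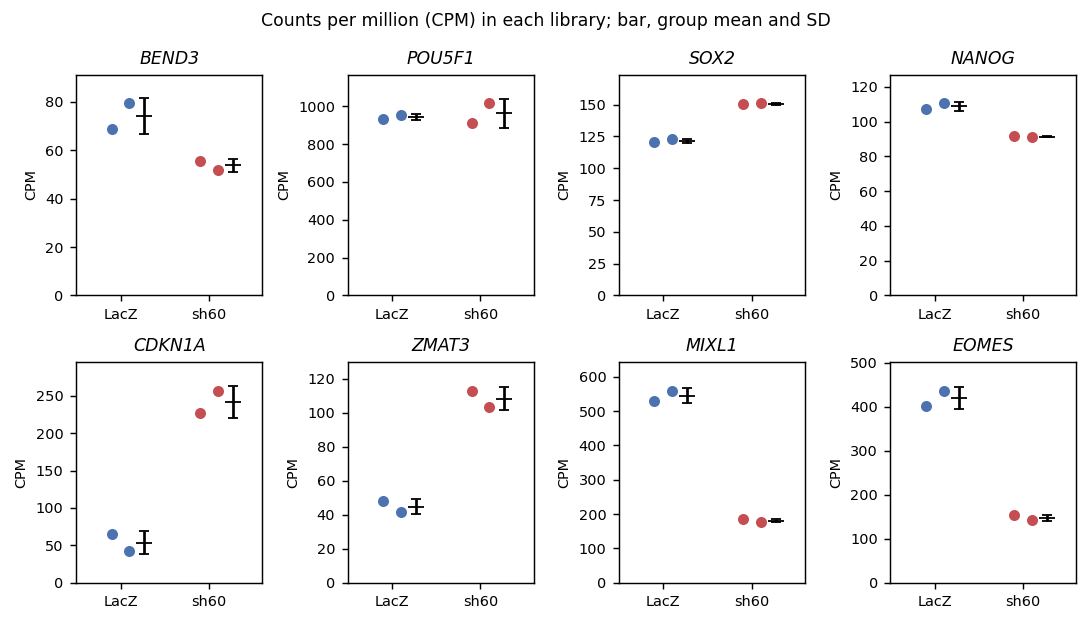
CPM (vertical axes, linear, starting at 0) of 8 named genes in the LacZ libraries (blue) and the sh60 libraries (red), 2 per group, with each group's mean and SD in black. BEND3 was lower in both sh60 libraries, POU5F1 overlapped between the groups, CDKN1A and ZMAT3 were higher in both sh60 libraries, and MIXL1 and EOMES were lower in both.

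Targets of p53 rose in the sh60 libraries. Of 40 tested members of the list, 32 rose, 0 fell and 8 did not pass the edgeR test (34 higher and 1 lower when adjusted over the list alone), with a median log2 fold change of 0.73. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, lies at chromosome 6, 36644237 to 36655116 (hg19). It went from 53.8 ± 15.6 CPM (SD, n = 2) in LacZ to 241.5 ± 21.5 CPM (SD, n = 2) in sh60, a 4.47-fold rise (log2 fold change 2.16, SE 0.14, edgeR adjusted p = 7.38e-09). ZMAT3, an RNA-binding protein induced by p53, rose 2.41-fold to 108.2 CPM, and GDF15, a secreted stress cytokine, rose 3.49-fold to 16.6 CPM. SPATA18, a mitochondrial quality control gene, rose 3.17-fold to 19.6 CPM. The list was higher as a set by camera with its preset correlation (adjusted p = 1.80e-23) and did not pass with an estimated correlation (adjusted p = 0.571 with an estimated correlation). Without LacZ replicate 3, 23 members were higher, and without sh60 replicate 2, 34 were higher and 1 was lower. With GC and length trends removed, 2 were lower. Of the 32, 30 were also higher in LacZ replicate 1 than in LacZ replicate 3, as were 230 of 254 large risers (90.6%). Large risers are called genes that rose by a log2 fold change of 1 or more at an average log2 CPM of 2 or more.

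Among 7 cyclin-dependent kinase inhibitor genes, 3 rose and 1 fell (3 and 1 when adjusted over the list alone). CDKN1B, CDKN2C and CDKN2D did not pass. The median log2 fold change was 0.12 and the mean 0.53, with the largest value, 2.16, in CDKN1A, which is also in the p53 list. Besides CDKN1A, CDKN2B rose from 13.8 to 31.6 CPM and CDKN2A rose from 1.34 to 2.68 CPM, while CDKN1C fell from 29.4 to 20.5 CPM. The set passed camera as higher (adjusted p = 0.0161; adjusted p = 0.571 with an estimated correlation), and not without sh60 replicate 2 (camera adjusted p = 0.0544). The CDKN2A call was lost without LacZ replicate 3 (edgeR adjusted p = 0.0504) and without sh60 replicate 2 (0.0609). The CDKN1C call was lost without LacZ replicate 1 (0.172).

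The genes of the dividing cell that passed the edgeR test were all lower in sh60, by modest amounts. Of 31 S-phase genes, 20 fell and 0 rose (23 and 0 when adjusted over the list alone), with a median log2 fold change of -0.31. UHRF1, which recruits the maintenance DNA methyltransferase to replicating DNA, went from 74.0 ± 3.15 to 38.9 ± 1.71 CPM (SD, n = 2 each), and MCM5, a subunit of the replicative helicase, from 166.7 ± 3.01 to 102.4 ± 13.1 CPM. Of 30 G2 and M phase genes, 14 fell and 0 rose (20 and 0 when adjusted over the list alone), with a median of -0.23. MKI67, the proliferation marker Ki-67, went from 524.5 to 347.7 CPM and TOP2A, a topoisomerase, from 766.7 to 554.9 CPM. Both lists were lower by camera (adjusted p = 9.91e-08 and 8.26e-06). Their p with an estimated correlation did not pass (adjusted p = 0.480 for S phase and adjusted p = 0.571 for G2 and M phase). The counts depended on the libraries and the scaling used. Without LacZ replicate 1, 10 S-phase and 5 G2 and M phase genes fell, without LacZ replicate 3, 8 and 4, and without sh60 replicate 1, 25 and 28. The G2 and M phase count was 21 by upper-quartile scaling and 30 of 30 with GC and length trends removed.

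The core pluripotency factors changed little. POU5F1, which encodes OCT4, measured 944.9 ± 14.8 CPM (SD, n = 2) in LacZ and 963.0 ± 74.8 CPM (SD, n = 2) in sh60, and did not pass (log2 fold change 0.03, SE 0.079, edgeR adjusted p = 0.835). Its 95% confidence interval of -0.14 to 0.19 on the log2 scale bounds any change. The sign of its value turned under upper-quartile scaling (-0.0022), without sh60 replicate 2 (-0.05) and with GC and length trends removed (-0.07). SOX2 rose 1.24-fold from 121.6 to 150.5 CPM (edgeR adjusted p = 0.00841), and NANOG fell from 108.8 to 91.3 CPM (edgeR adjusted p = 0.0332). The log2 fold changes were 0.31 for SOX2 and -0.25 for NANOG. They were 0.30 and -0.27 without LacZ replicate 1, and 0.32 and -0.23 without LacZ replicate 3. Both calls were lost in these 2 fits, which leave 1 LacZ library, although the effects hardly moved. NANOG was also not called with library totals only (edgeR adjusted p = 0.0553). Over the alternatives the adjusted p ran from 0.000271 to 0.208 for SOX2, from 0.000382 to 0.420 for NANOG and from 0.133 to 0.988 for POU5F1. Reads of POU5F1 and NANOG can be shared with their processed pseudogenes, and POU5F1 is annotated on alternative haplotype sequences as well as chromosome 6, so both levels are uncertain.

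Of 31 tested pluripotency genes, 12 fell, 3 rose and 16 did not pass (13 and 3 when adjusted over the list alone), with a median log2 fold change of -0.16. DNMT3B, a de novo DNA methyltransferase high in pluripotent cells, fell from 918.3 ± 54.6 to 559.4 ± 19.3 CPM (SD, n = 2 each), and GAL, the neuropeptide galanin, from 148.4 to 84.6 CPM. NODAL, a signalling ligand of the early embryo, fell from 44.9 to 26.4 CPM and FGF4, a growth factor, from 10.6 to 4.83 CPM. The 3 that rose were SOX2, DPPA3 and LEFTY1, the last 2 of them named after their values were seen. The list was lower by camera (adjusted p = 0.00446; adjusted p = 0.571 with an estimated correlation) and by fry (adjusted p = 0.0318). With LacZ replicate 3 left out, 8 members fell and 1 rose.

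Among the lineage lists, that of mesoderm and primitive streak genes had the smallest p by camera with its preset correlation. Differences between lists were not tested. Of 29 tested members, 14 fell, 5 rose and 10 did not pass (14 and 7 when adjusted over the list alone). MIXL1 (chromosome 1, 226411319 to 226414756, hg19), a homeobox gene of the primitive streak, fell from 544.2 ± 21.7 to 180.9 ± 5.37 CPM (SD, n = 2 each), a level 3.01-fold lower (log2 fold change -1.59, SE 0.081, edgeR adjusted p = 2.24e-09). EOMES (chromosome 3, 27757440 to 27764206), a T-box factor of mesendoderm, fell 2.83-fold from 419.0 to 148.0 CPM. TBXT, which encodes brachyury and is listed under its older symbol T (chromosome 6, 166571146 to 166582157), fell 3.85-fold from 104.8 to 27.2 CPM. TBX6, a factor of presomitic mesoderm, fell 3.66-fold from 15.98 to 4.33 CPM. The 5 members that rose were TBX5, RUNX1, ACTC1, MEF2C and HAND1, which were named after their values were seen. The list was lower by camera (adjusted p = 7.05e-07; adjusted p = 0.571 with an estimated correlation). Between 13 and 14 members fell when any 1 library was left out.

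The other lineage lists moved in both directions. Of 14 tested endoderm genes 4 fell and 1 rose (4 and 1 when adjusted over the list alone). CDX2 fell from 23.9 to 6.76 CPM, GSC from 5.24 to 1.76 CPM, GATA6 from 45.3 to 25.98 CPM and GATA4 from 25.3 to 14.7 CPM, while KRT19 rose. Camera gave this list as lower (adjusted p = 0.0371; adjusted p = 0.571 with an estimated correlation), but not without LacZ replicate 1 (0.129), without sh60 replicate 1 (0.168), without sh60 replicate 2 (0.0844) or with GC and length trends removed (0.157). Of 25 neural ectoderm genes, 11 rose and 5 fell (11 and 5 when adjusted over the list alone), and the list did not pass camera (adjusted p = 0.118). SNAP25, a synaptic vesicle fusion protein, rose 5.09-fold from 1.29 to 6.53 CPM and MAP2, a neuronal microtubule protein, 1.83-fold to 113.5 CPM. The homeobox genes GBX2 and LHX2 fell from 34.9 to 13.7 CPM and from 43.7 to 21.9 CPM. Fewer neural genes, 7, rose without LacZ replicate 3. Of 9 trophoblast genes 2 rose and 1 fell (3 and 2 when adjusted over the list alone). KRT7 rose 2.17-fold, TFAP2A rose 1.29-fold and CDX2 fell. That list did not pass camera (adjusted p = 0.924), whose direction was down although the median was 0.23 and the mean 0.0090. TFAP2A was not called without LacZ replicate 3 (edgeR adjusted p = 0.484), without sh60 replicate 1 (0.0765), without sh60 replicate 2 (0.0576) or by DESeq2 (0.0878), and 4 trophoblast genes rose without sh60 replicate 1 or with no count filter.

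Families of developmental transcription factors fell more often than they rose. Of 156 tested members 41 fell and 18 rose (47 and 20 when adjusted over the list alone). CDX1 fell from 41.7 to 13.7 CPM and MSX1, also in the list of TGF-beta and BMP targets, from 171.1 to 77.7 CPM. TBX6, CDX2, GATA6, GATA4, GBX2 and LHX2, which fell, and SOX2, which rose, are also members of lists given above. The falls in this list are therefore in part the same as those above. Camera placed the list lower (adjusted p = 0.0114; adjusted p = 0.571 with an estimated correlation), but not without LacZ replicate 1 (0.0567), without sh60 replicate 1 (0.0850) or with GC and length trends removed (0.105). With LacZ replicate 3 left out, 28 fell and 11 rose. Of 29 HOX genes within this group 5 fell and 1 rose (5 and 1 when adjusted over the list alone), and the set did not pass (camera adjusted p = 0.158). HOXD1 fell from 6.04 to 3.05 CPM. In the fit without LacZ replicate 3, 3 HOX genes fell and 0 rose, and 8 fell by upper-quartile scaling or with no count filter.

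**Figure D2:**
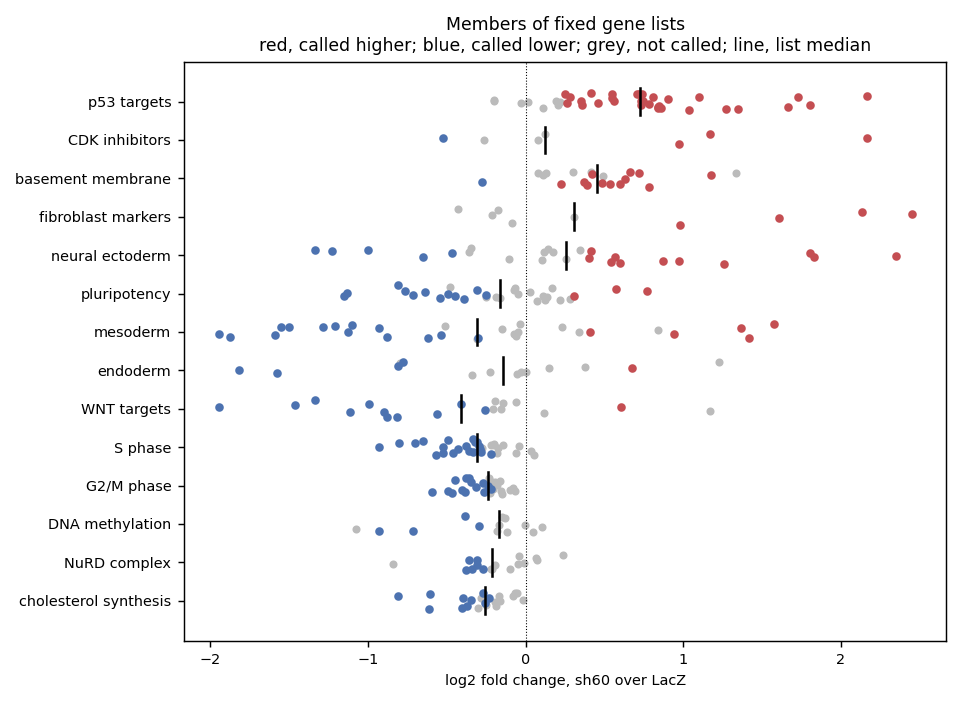
Log2 fold change (horizontal axis, sh60 over LacZ) of each tested member of 14 gene lists, with members called higher in red, members called lower in blue, members not called in grey and the list median as a black line. Of the p53 targets 32 of 40 were called higher, and of the mesoderm list 14 of 29 were called lower.

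More WNT targets fell than rose. Of 19 tested targets 11 fell and 1 rose (13 and 2 when adjusted over the list alone), with a median log2 fold change of -0.41. AXIN2, a negative feedback gene of the pathway, fell from 118.0 ± 5.55 to 64.2 ± 1.42 CPM (SD, n = 2 each), TCF7, a pathway transcription factor, from 84.6 to 42.5 CPM, and NKD1, another feedback gene, from 219.4 to 124.6 CPM. TBXT belongs to this list as well as to the mesoderm list. The list was lower by camera (adjusted p = 7.10e-08; adjusted p = 0.480 with an estimated correlation) and by fry (adjusted p = 0.0303), and 8 members fell without LacZ replicate 3. Of 12 WNT ligand genes 5 fell and 1 rose (5 and 1 when adjusted over the list alone). WNT3, which is also in the mesoderm list, fell from 65.0 to 28.1 CPM. WNT3A fell from 8.37 to 2.35 CPM and WNT8A from 13.6 to 4.96 CPM, while WNT4, named after its value was seen, rose. Camera gave the ligands as lower (adjusted p = 0.00848; adjusted p = 0.571 with an estimated correlation), although their median was 0.0095 and their mean -0.26. With LacZ replicate 1 left out, 3 ligands rose, and without LacZ replicate 3 or without sh60 replicate 2, 0 rose.

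Other signalling lists did not pass camera as sets. Of 17 NOTCH pathway genes 8 fell and 3 rose (8 and 4 when adjusted over the list alone; camera adjusted p = 0.0744). The ligand gene DLL3 fell from 30.6 to 11.3 CPM. Without LacZ replicate 3 this list passed (0.0226), with 6 lower and 1 higher, and without LacZ replicate 1, 5 fell. By DESeq2 4 fell, and without sh60 replicate 1, 5 rose. Of 21 TGF-beta and BMP targets 8 rose and 4 fell (8 and 4 when adjusted over the list alone; camera adjusted p = 0.571). TGFBI rose 2.64-fold to 67.5 CPM, while ID3 fell from 262.5 to 155.4 CPM. The median of that list was -0.045 and its mean 0.12, and without LacZ replicate 3, 4 rose and 4 fell. Of 18 retinoic acid response genes 5 rose and 7 fell (5 and 7 when adjusted over the list alone; camera adjusted p = 0.687). NR2F2 rose 2.96-fold to 4.99 CPM and STRA6 fell from 70.0 to 31.2 CPM. With LacZ replicate 3 left out, 3 rose and 4 fell. The mean of this list was 0.0087 and its median -0.053.

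Among genes of the chromatin complexes that BEND3 has been linked with, more fell than rose. Of 17 NuRD complex genes 6 fell and 0 rose (8 and 0 when adjusted over the list alone), with a median log2 fold change of -0.21. ZMYND8 fell from 240.3 to 184.7 CPM and RBBP4 from 764.2 to 604.4 CPM. The set passed camera as lower (adjusted p = 0.0371; adjusted p = 0.571 with an estimated correlation), but not without LacZ replicate 1 (0.0552; 1 lower), without LacZ replicate 3 (0.108; 0 lower) or with the stricter count filter (0.0525). Without sh60 replicate 1, 2 NuRD genes rose. The calls of ZMYND8 and RBBP4 were lost without LacZ replicate 3, with log2 fold changes of -0.32 and -0.33 against -0.38 and -0.34 in the main fit. That of RBBP4 was also lost without LacZ replicate 1, at -0.34. Of 14 PRC2 genes 4 fell and 1 rose (4 and 1 when adjusted over the list alone; camera adjusted p = 0.218). C17orf96, also called EPOP, fell from 13.9 to 5.69 CPM. Without LacZ replicate 1 or without LacZ replicate 3, 1 PRC2 gene fell, and without sh60 replicate 1, 7 fell. Of 13 DNA methylation genes 4 fell and 0 rose (4 and 0 when adjusted over the list alone), among them UHRF1 and DNMT3B. That set was lower by camera (adjusted p = 0.00808; adjusted p = 0.571 with an estimated correlation), with 2 lower when either LacZ library was left out and 7 lower without sh60 replicate 1 or with GC and length trends removed.

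Among 7 BEN-domain and related genes 2 fell and 1 rose (3 and 2 when adjusted over the list alone; camera adjusted p = 0.924). Beside BEND3, NACC1 fell from 395.5 to 324.3 CPM and NACC2 rose from 79.3 to 131.3 CPM. The NACC1 call was lost without LacZ replicate 1 and without LacZ replicate 3. Its log2 fold change was -0.30 and -0.27 in these fits, against -0.29 in the main fit. Of 32 ribosome biogenesis genes 2 fell and 1 rose (2 and 1 when adjusted over the list alone; camera adjusted p = 0.0804). These were RRN3 and NIP7, lower, and BAZ2A, higher, and 0 were called without LacZ replicate 1 or without LacZ replicate 3. The set passed camera without sh60 replicate 1 (0.0241; 12 lower) and with GC and length trends removed (0.0373; 15 lower), and 8 fell without sh60 replicate 2 and 6 by upper-quartile scaling. Of 13 germline genes 4 fell and 2 rose (4 and 2 when adjusted over the list alone; camera adjusted p = 0.323). MAEL rose 3.02-fold from 0.696 to 2.15 CPM. Without LacZ replicate 1, 1 germline gene fell, and without LacZ replicate 3, 2 fell.

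The genes with the largest rises were mostly low in the LacZ libraries, and those with the largest falls had a mean of at least 5 CPM there, as the naming rule requires. The 10 largest rises had log2 fold changes of 2.58 to 3.61 and the 10 largest falls -2.44 to -1.90. PTHLH, the parathyroid hormone related peptide (chromosome 12, 28111017 to 28124916, hg19), rose 12.2-fold from 0.608 ± 0.248 to 7.73 ± 1.63 CPM (SD, n = 2 each; log2 fold change 3.61, SE 0.25, edgeR adjusted p = 1.98e-08). The other large rises were CPA4, MAP3K7CL, FLG, C4orf26, SERPINB7, NPPB, MFAP5, RRAD and NNMT. They include FLG, which encodes the epidermal protein filaggrin, NPPB, a natriuretic peptide, and MFAP5, a microfibril protein that rose 7.71-fold to 62.0 CPM. In all 10, LacZ replicate 1 lay above LacZ replicate 3. Leaving out LacZ replicate 1, the fold change grew by more than 1.5 times for 7 of them, to a log2 fold change given here in parentheses: CPA4 (4.44), MAP3K7CL (4.32), FLG (4.13), C4orf26 (4.17), MFAP5 (3.87), RRAD (3.56) and NNMT (4.01). The largest fall was PCSK1, a prohormone convertase (chromosome 5, 95726040 to 95768985), from 20.04 ± 2.52 to 3.70 ± 0.455 CPM (SD, n = 2 each; 5.43-fold lower, SE of the log2 value 0.15, edgeR adjusted p = 6.51e-09). EDAR, ISLR, PCDHGC4, GAL3ST1, MATN3, TBXT, CST1, TNFRSF1B and DES followed. In these falls LacZ replicate 1 lay below LacZ replicate 3, on the side of the sh60 libraries, except for MATN3. Of the 128 genes that fell by the cutoffs of the large risers, 82 (64.1%) lay on that side. PCDHGC4 shares its last exons with the other gamma protocadherins and CST1 resembles other cystatin genes, so their counts are uncertain.

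**Figure D3:**
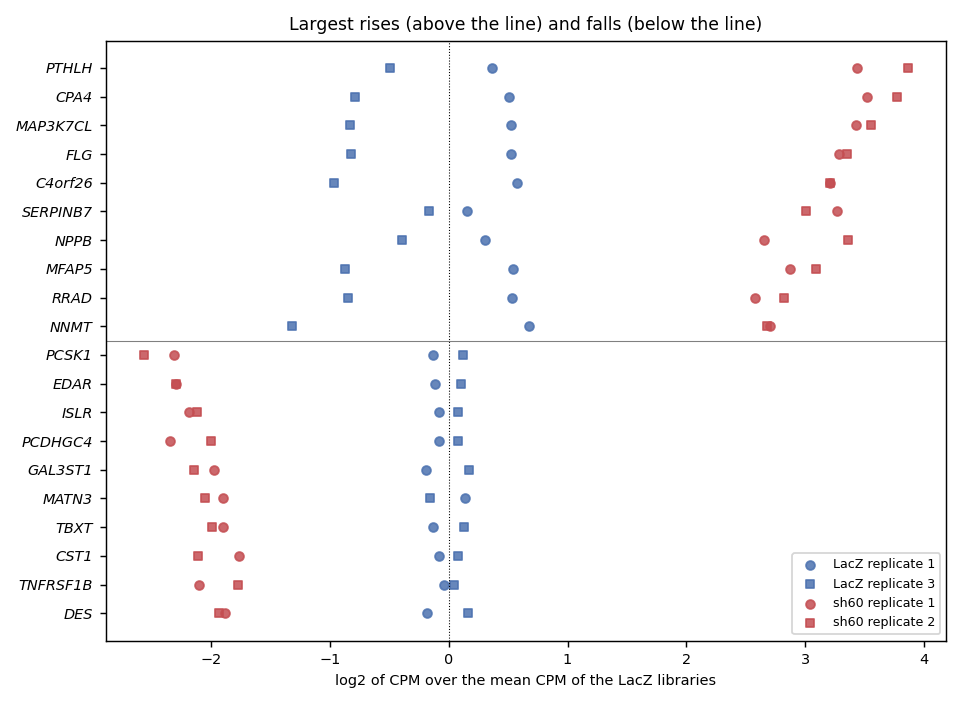
Log2 ratio (horizontal axis) of each library's CPM to the mean CPM of the LacZ libraries for the 10 largest rises (above the line) and the 10 largest falls (below it), with LacZ libraries in blue and sh60 libraries in red. Both sh60 libraries lay beyond both LacZ libraries for each gene. LacZ replicate 1 (blue circles) lay above LacZ replicate 3 (blue squares) in the 10 rises, and below it in the falls except for MATN3.

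Markers of other cell types and signs of RNA quality were measured beside these groups. Of 9 fibroblast markers 4 rose and 0 fell (4 and 0 when adjusted over the list alone). COL1A1, the main chain of type I collagen, rose 5.46-fold from 113.1 ± 39.97 to 618.9 ± 92.2 CPM (SD, n = 2 each), COL1A2 4.39-fold to 73.4 CPM, LUM 3.05-fold to 27.7 CPM and POSTN 1.97-fold to 4.13 CPM. The set passed camera (adjusted p = 0.000316; adjusted p = 0.571 with an estimated correlation). A further pair of fibroblast transcripts, COL3A1 and COL6A3, were at 11.8 and 33.9 CPM in LacZ and at 8.82 and 32.0 CPM in sh60. The log2 fold change of LUM was 2.27 without LacZ replicate 1, and 2 fibroblast markers were lower without sh60 replicate 2. Of 5 blood markers 1 rose and 1 fell, LYZ and CD74, both below 1 CPM and neither of them called by DESeq2 (1 and 1 when adjusted over the list alone; camera adjusted p = 0.844). Once LacZ replicate 1 was left out, neither passed.

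Ribosomal protein genes took 4.94% and 5.14% of counts in the LacZ libraries and 4.30% and 4.82% in the sh60 libraries. Of 77 tested, 16 fell and 1 rose (16 and 1 when adjusted over the list alone), and the set was lower by camera (adjusted p = 0.000533; adjusted p = 0.729 with an estimated correlation). RPL27A fell from 735.4 to 391.6 CPM, and the gene that rose, RPS27L, is a p53 target. The number that fell was 9 without LacZ replicate 1, 3 without LacZ replicate 3, 50 without sh60 replicate 2, 24 by upper-quartile scaling and 36 with GC and length trends removed. Without sh60 replicate 1, 4 rose and the set did not pass (0.0729). Ribosomal protein genes have many pseudogenes, so their counts are uncertain. Of 29 histone genes of the clusters 4 rose and 2 fell (4 and 2 when adjusted over the list alone; camera adjusted p = 0.347), and they took 0.00484% and 0.00465% of counts in the LacZ libraries and 0.00625% and 0.00684% in the sh60 libraries. In the fit without LacZ replicate 3, 2 of them rose and 0 fell, and without sh60 replicate 2, 0 fell. The 10 most abundant genes, led by GAPDH, EEF1A1 and ACTB, took 4.43% and 4.41% of counts in the LacZ libraries and 3.78% and 4.13% in the sh60 libraries. Each of these 3 shares therefore separated the groups, the histone share being higher in sh60 and the other 2 lower. The smallest exact permutation p for 2 libraries against 2 is 0.333, so these shares were not tested.

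Of 41 lists tested, 20 passed camera with the preset correlation, 7 higher and 13 lower. With an estimated correlation 0 passed, and by fry, which asks whether the members move one way on balance, 3 passed. These 3 were the pluripotency, S-phase and WNT target lists. In simulated data a set of 30 genes all raised 1.5-fold had an unadjusted p of 0.00572 by camera with an estimated correlation. The smallest such p among the lists here was 0.0222, for S phase. Estimated with 2 residual degrees of freedom and adjusted over 41 lists, that test can miss a real shift. A list that did not pass it was therefore not shown to be unchanged. Of 46 tests of called genes by chromosome and direction, 7 passed Fisher's exact test, two-sided. The clearest was chromosome 19, where 104 of 1122 tested genes (9.27%) were higher in sh60, against 16.3% elsewhere (odds ratio 0.523, adjusted p = 1.83e-09). Higher genes were also less frequent on chromosomes 17 and 22. Lower genes were less frequent on chromosomes 3 and 6 and more frequent on chromosomes 12 and 22. Genes are not independent replicates. Among genes with a mean of 1 CPM or more 2 passed, and with GC and length trends removed 1 did, chromosome 19.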

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

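The removal of GC and length trends was chosen after the results were seen; all the other alternatives in this part were fixed before the data were examined. The number of changed genes ran from 2287 to 5486 when 1 library was left out (lowest without LacZ replicate 3), those higher from 1331 to 2789 and those lower from 956 to 2697. A test against a fold of 1.2 called 2283 genes. Removing GC and length trends called 3695 genes as lower and 2916 as higher, so that 44.1% of calls were higher against 54.9% in the main analysis. With upper-quartile scaling this share was 48.5% (2424 higher and 2575 lower), and with library totals only it was 60.1%. The cause of these shifts was not tested, beyond the fewer libraries. DESeq2 called 3756 genes, all of them among the 4624, and other settings 4461 to 4999. Leaving out a library leaves 1 sample in its group, which is then assumed to vary like the other group. A call lost in such a fit can come with a nearly unchanged effect, as for SOX2, NANOG, RBBP4 and NACC1. BEND3 stayed lower in every setting, with log2 fold changes of -0.56 to -0.36 when 1 library was left out, and lost its call without LacZ replicate 3 (-0.36).

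Of 41 lists, 20 passed with the preset correlation, 0 with an estimated correlation and 3 by fry. Of 46 chromosome tests 7 passed, against 2 among genes of 1 CPM or more and 1 with GC and length trends removed. POU5F1 turned direction under upper-quartile scaling (-0.0022), without sh60 replicate 2 (-0.053, in a range up to 0.10 when 1 library was left out) and with GC and length trends removed (-0.072). Lists that turned direction did not pass on either side. These were trophoblast genes by fry (adjusted p = 0.954), without LacZ replicate 1 (0.707), without sh60 replicate 1 (0.4997) and with GC and length trends removed (0.786), TGF-beta and BMP targets (0.912) and unfolded protein genes (0.896) without LacZ replicate 3, and blood markers (0.963) without sh60 replicate 1. With each library left out in turn, their adjusted p ran from 0.0862 to 0.912 for the TGF-beta and BMP targets, 0.633 to 0.896 for the unfolded protein genes, 0.912 to 0.996 for the blood markers and 0.4997 to 0.896 for the trophoblast genes. The cause was not tested. Of 162 named genes beside BEND3, 39 lost or gained a call or turned direction in at least 1 setting, among them 1 that turned, and the others kept direction and call. The change of each gene's log2 fold change from the main analysis had a median of -0.045 with GC and length trends removed, the largest of any setting. No paired analysis was possible because the groups share only replicate number 1. Leaving out mitochondrially encoded genes was not run, since no such genes are listed. Depth limits mainly the low genes: KRT74 and HES7, called lower, lay below 1 CPM.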

Other observations

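Basement membrane genes were higher in sh60 more often than lower. Of 20 basement membrane genes 12 rose and 1 fell (13 and 1 when adjusted over the list alone; camera adjusted p = 8.26e-06, adjusted p = 0.571 with an estimated correlation). COL4A2, a chain of the basement membrane collagen, went from 196.0 ± 16.5 to 443.9 ± 11.1 CPM (SD, n = 2 each), and LAMB2, a laminin chain, from 79.8 to 137.1 CPM. With LacZ replicate 3 left out, 6 of these genes rose. Of 42 collagen genes 15 rose and 5 fell (16 and 6 when adjusted over the list alone; camera adjusted p = 0.000221, adjusted p = 0.571 with an estimated correlation). COL12A1 rose 4.60-fold to 92.4 CPM, with a log2 fold change of 2.20, or 2.80 without LacZ replicate 1. Of 20 mesenchymal genes 8 rose and 4 fell (8 and 4 when adjusted over the list alone). TAGLN, an actin-binding protein of smooth muscle, rose from 223.5 to 627.5 CPM and FN1, fibronectin, from 850.0 to 1844 CPM, while SNAI1, a factor of epithelial to mesenchymal transition, fell from 43.5 to 16.1 CPM. The mesenchymal set passed camera (adjusted p = 0.0195; adjusted p = 0.729 with an estimated correlation), but not without LacZ replicate 3 (0.0778), without sh60 replicate 2 (0.0506) or with GC and length trends removed (0.0937). With LacZ replicate 1 left out, 1 mesenchymal gene fell, and without LacZ replicate 3, 2 fell. Of 20 epithelial genes 7 rose and 1 fell (9 and 3 when adjusted over the list alone; camera adjusted p = 0.249). ESRP2, a splicing factor of epithelial cells, rose 1.69-fold to 15.0 CPM. The gene that fell was CDH1, from 131.5 to 102.8 CPM (log2 fold change -0.35, edgeR adjusted p = 0.00414). Its call was lost without LacZ replicate 1 (log2 fold change -0.40) and without LacZ replicate 3 (-0.30). Without LacZ replicate 1 or without sh60 replicate 2, 3 epithelial genes rose, and without LacZ replicate 3, 4 rose. Epithelial genes that fell numbered 3 when either sh60 library was left out, by upper-quartile scaling and with GC and length trends removed. Of 11 keratin genes 3 rose and 2 fell (3 and 3 when adjusted over the list alone; camera adjusted p = 0.683), with a median of 0.14 and a mean of -0.30. In the fit without LacZ replicate 1, 0 keratin genes fell, as by DESeq2, and 4 fell with GC and length trends removed.

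Metabolic and stress genes moved in smaller groups. Of 22 cholesterol synthesis genes 10 fell and 0 rose (15 and 0 when adjusted over the list alone; camera adjusted p = 8.77e-05, adjusted p = 0.571 with an estimated correlation). HMGCS1, an early enzyme of the pathway, went from 199.5 ± 18.0 to 130.5 ± 11.2 CPM (SD, n = 2 each). The number that fell was 3 without LacZ replicate 3, 6 by DESeq2 and 18 with GC and length trends removed. Of 26 hypoxia and glycolysis genes 7 rose and 2 fell (8 and 2 when adjusted over the list alone; camera adjusted p = 0.0202, adjusted p = 0.571 with an estimated correlation). ADM, the vasodilator peptide adrenomedullin, rose 4.59-fold to 58.3 CPM and P4HA2, a collagen prolyl hydroxylase, 3.83-fold to 22.4 CPM. In this list 4 rose without LacZ replicate 3, 1 fell when either LacZ library was left out, and 5 fell without sh60 replicate 2. Of 28 interferon response genes 5 rose and 9 fell (6 and 9 when adjusted over the list alone; camera adjusted p = 0.218). IFITM3 fell from 214.3 to 121.7 CPM and IFITM1 from 216.5 to 134.1 CPM. The IFITM genes are close copies, so their counts are uncertain. Without LacZ replicate 3, 2 interferon response genes rose, and without LacZ replicate 1 or without sh60 replicate 2, 3 rose. Of 21 immediate early genes 8 rose and 5 fell (8 and 6 when adjusted over the list alone; camera adjusted p = 0.210), ATF3 and JUN among the risers, and 2 fell when either LacZ library was left out. Integrated stress genes were split, with 8 of 22 higher and 8 lower (9 and 8 when adjusted over the list alone; camera adjusted p = 0.494, up, with a median of -0.037). With LacZ replicate 1 left out, 1 of them fell, and without LacZ replicate 3, 2 fell and 5 rose. By DESeq2 5 fell. Of 18 unfolded protein genes 1 rose, EDEM1, and 0 fell (1 and 0 when adjusted over the list alone; camera adjusted p = 0.844). EDEM1 lost its call without LacZ replicate 3 (edgeR adjusted p = 0.0689), and 3 genes of this list rose without sh60 replicate 1 and 5 without sh60 replicate 2. In that fit, and with GC and length trends removed, 3 fell. Of 14 heat shock genes 2 rose and 3 fell (2 and 3 when adjusted over the list alone; camera adjusted p = 0.347), with 7 lower without sh60 replicate 1, 5 without sh60 replicate 2, 0 without LacZ replicate 1 and 1 without LacZ replicate 3. By upper-quartile scaling 5 fell, and with GC and length trends removed 9. Of 21 imprinted genes 6 rose and 3 fell (6 and 3 when adjusted over the list alone; camera adjusted p = 0.425). MEST rose 2.43-fold to 59.5 CPM, and IGF2, whose reads overlap a read-through gene, rose 2.80-fold to 4.72 CPM. With LacZ replicate 3 left out, 2 imprinted genes rose, and without LacZ replicate 1, 3 rose and 0 fell. With GC and length trends removed 5 fell. Of 35 clustered protocadherin genes 8 fell and 1 rose (8 and 1 when adjusted over the list alone; camera adjusted p = 0.0371, adjusted p = 0.571 with an estimated correlation), which share exons. That set did not pass without LacZ replicate 1 (0.129), without sh60 replicate 1 (0.103), without sh60 replicate 2 (0.153) or with GC and length trends removed (0.118). Of 459 genes named as zinc finger proteins 39 fell and 20 rose (20 and 15 when adjusted over the list alone; camera adjusted p = 0.295). Of all tested genes 13.0% fell and 15.8% rose, so calls were less frequent in this family. ZNF469 rose 2.41-fold to 22.5 CPM. The counts were 12 lower and 12 higher without LacZ replicate 1, 10 and 7 without LacZ replicate 3, and 36 and 36 without sh60 replicate 2. Without sh60 replicate 1, 76 fell and the set passed as lower (0.0301). By upper-quartile scaling 61 fell, and with GC and length trends removed 108. The single tested cancer-testis gene, MAGEB3, did not pass (log2 fold change -0.41, edgeR adjusted p = 0.104), and passed without sh60 replicate 1 (0.0231) and with GC and length trends removed (0.0328).

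Of the tests that follow, those of GC and length bias and of YAP and TAZ targets were set before their result was seen, although the YAP and TAZ list itself was written after the data; all the others were chosen after the result was seen. The first pattern is the rise of p53 targets. Release of CDKN1A alone from repression is argued against by 31 of the 39 other members being higher and 0 lower. A GC or length trend is argued against by all 32 of 32 called members staying higher once those trends were removed. Of all 4624 called genes, 4549 likewise kept their call and direction, so this is not particular to p53 targets. A culture state that differed between plates could contribute: 30 of the 32 (93.8%) were also higher in LacZ replicate 1 than in LacZ replicate 3. The same held for 230 of the 254 large risers (90.6%), and the share is therefore not particular to p53 targets. With 2 libraries per group such a state cannot be separated from the group. A p53 response to lower BEND3 or to the hairpin itself stays open and was not tested, since a single hairpin was used.

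The second pattern is the members of the mesenchymal, fibroblast and basement membrane lists that rose, although 4 mesenchymal genes and 1 basement membrane gene fell. Fibroblasts among the sh60 cells stay open. COL3A1, DCN and COL6A3 together changed by -4.36 CPM while COL1A1 gained 505.7 CPM, which speaks only against fibroblasts rich in all of these transcripts. The genes were chosen after their values were seen, and 4 of 9 markers of the fixed fibroblast list rose and 0 fell. Higher YAP and TAZ activity may take part: 10 of 16 targets whose values had not been seen were higher and 1 lower (camera p = 6.94e-10; p = 0.162 with an estimated correlation), AXL rising 3.34-fold to 66.5 CPM and F3 2.28-fold to 67.7 CPM. Of 24 called risers of the mesenchymal, fibroblast and basement membrane lists, 22 (91.7%) were higher in LacZ replicate 1 than in LacZ replicate 3. So were 16 of the 16 YAP and TAZ targets and 90.6% of the 254 large risers. A culture difference and an effect of the hairpin therefore cannot be told apart with 2 libraries per group.

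The third pattern is the fall of 14 of 29 tested mesoderm genes, although 5 rose and 10 did not pass. Dilution of NTERA2 cells by another cell type would lower POU5F1, NANOG and SALL4 as well. Their lowest 95% confidence bound was -0.48 on the log2 scale, against a median of -1.17 over the 14 members that fell. This argues against dilution alone for a fall of that size, although the levels of POU5F1 and NANOG are uncertain. It does not cover the whole list, since the 14 were picked by their fall and the median of all 29 was -0.31. A culture difference stays open, although this pattern did not lean between the LacZ libraries as the p53 and matrix risers did. Of the 14 members, 6 (42.9%) were lower in LacZ replicate 1 than in LacZ replicate 3. Their median log2 difference, LacZ replicate 1 minus LacZ replicate 3, was 0.030 (quartiles -0.084 and 0.20), while a shared culture state would need a negative value. The proportion seen in the 254 large risers would need -0.39. That seen in the 128 genes that fell by the same cutoffs would need -0.077, and some of those genes are members of this list. The lower quartile reached the second of these values and not the first. Lower canonical WNT signalling also stays open. Of 18 WNT targets outside the mesoderm list 10 fell and 1 rose (camera p = 1.34e-06; p = 0.0347 with an estimated correlation, neither adjusted over the lists). These genes make up all but 1 of the full list, whose counts were known before the test was written (camera adjusted p = 7.10e-08; adjusted p = 0.480 with an estimated correlation), so the test adds no support of its own. Whether the fall follows from BEND3 or from another effect of the hairpin was not tested.

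Genes higher in sh60 were less frequent on chromosome 19 also with GC and length trends removed (12.7% against 18.6% elsewhere, odds ratio 0.634, Fisher's exact test adjusted p = 1.20e-05). The median GC content of genes was 58.4% there against 48.1% on other chromosomes. The cause of the lower share was not tested, and the part that gene families of this chromosome take in it was not counted.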
